A study of Homo sapiens with 8 samples.

How the data were processed

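RNA-seq was carried out on primary human aortic endothelial cells, the cells that line the aorta. Cells had received a small interfering RNA (siRNA) against REST or a scramble control siRNA, and 4 libraries were made per group. RNA was extracted with a Qiagen micro-column kit, per the labels' protocols. All 8 libraries carry the same batch number in the labels. The table's columns show the group of each library but carry none of the labels' library names, so replicate numbers here only name a column. The labels do not say whether the libraries of a group came from separate cultures or donors. The p-values therefore measure the spread between these libraries, which may be technical.

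The authors deposited 1 table of expected counts per gene for the 8 libraries, and RSEM is the counter that the table's own name gives. Expected counts are estimates that share reads among genes and isoforms they match, so they need not be whole. Of the values above 0, 87.7% were whole within 0.005. The aligner, the RSEM version, the genome build and the strandedness of the libraries are not given in the sources used here. The submitters' processing notes name DESeq2, with no version or role. All 58780 gene IDs of the table, versions included, are in GENCODE release 29 (GRCh38), which supplied positions, gene types, exonic lengths and 3' UTRs. Symbols came from that annotation and from a table of current gene names, which held 58252 of the IDs. Y-linked genes, XIST and TSIX, 565 IDs in all, were left out of every test.

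Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a count minimum of 10, which left 14355 of 58215 genes. TMM factors ranged from 0.970 to 1.04. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of REST siRNA against control, with no covariate and Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p below 0.05. Levels are CPM, counts scaled to a common library total, on TMM-scaled library sizes, as mean ± SD over 4 libraries. Positive log2 fold changes mean higher in REST siRNA cells, and each has its standard error (SE). Where a gene had no count in any control library, its fold is a lower bound against a floor of 3 counts over the 4 libraries. Where it had 1 to 3 counts, the ratio of counts is given with its exact 95% interval. These intervals and floors cover counting error only. The interval of REST instead spans 1.96 SE on either side of its log2 fold change, and so includes the spread between libraries.

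Totals of 25787298 to 32327201 expected counts per library put the value of 3 counts at 0.0923 to 0.12 CPM. The common biological coefficient of variation was 7.54%. Replicates were compared before use. Over genes with at least 20 counts in a pair, chi-square per gene lay between 5.1 and 15.7 in the pairs within a group. Every pair thus differed by more than sampling noise, and no library was counted as a repeat of another. Correlations of log2 CPM across genes within these pairs ranged from 0.985 to 0.993.

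Before the data were examined, 30 gene lists with 964 members were fixed from textbook knowledge, together with the rule for named genes. The rule takes REST, the 10 largest rises and the 10 largest falls, and up to 4 members per list. Largest changes were taken among changed protein-coding genes with a mean of at least 1 CPM, groups that did not overlap, and a symbol that is no clone or locus name. List members were those with the smallest adjusted p among the changed ones. A gene chosen after its values were seen is marked as such. Some genes that the rule takes are not reported here. Of the members, 962 had a gene ID. The 28 lists with at least 5 measured members were tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. It was repeated with a correlation estimated per list, and fry, which asks whether a list's genes move one way on balance, was run beside it. Counts of members that rose or fell are from edgeR over all genes, with counts adjusted over the list alone beside them.

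Alternatives were DESeq2 size factors, library size only, no low-count filter, a mean of at least 5 CPM, DESeq2 (1.42.0), limma voom, libraries thinned to the smallest total, and each library left out in turn. A correction for each library's trend on GC content and exonic length (99.95% of tested genes had a GC value) and the removal of genes with certain 3' UTR heptamers were added after seeing the data. To look for siRNA-like or microRNA-like effects, the presence of each of 16224 heptamers with at least 50 genes was related to the ranked fold change over 12443 genes. That test used each gene's longest annotated 3' UTR and removed effects of UTR length and dinucleotide content. The lowest and highest z of 100 permutations of the fold changes over genes served as limits. These steps used Python 3 with numpy, pandas and scipy.

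The tests were also tried on simulated data, built from the fit of the real data. Counts were simulated from the control means and from the dispersions and totals of the comparison of REST siRNA with control, and 13976 genes were tested. In that simulation edgeR recovered 74.6% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 93.9% of those changed 4-fold. It also called 16 unchanged genes, 8.99% of its calls. Only 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, against 8008 genes called in the real data. These rates therefore need not carry over to the real comparison. A heptamer planted in the fold changes of 114 genes, after shuffling these over genes, ranked 1 by z. The planted shift was larger than the median shifts of the heptamers reported below, so it does not show how weaker effects would rank.

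Without stated strandedness, reads of genes that overlap on opposite strands cannot be told apart. This concerns REST (with NOA1), CMPK2 and RSAD2 (with each other), CTBP2, ACTA2, IRF1, FOXM1, MCM7, STAB1, LIPA, IGFBP7, MCAM, TMEM198, SLC7A11, PDIA6, HSP90B1, TP53I3, XPC, JUNB, DNAJB1 and CLDN7. Counts of MMRN2, NOTCH2, PGAM1, CD68, RPL3, HSPA1B, RGS5, RAB3D, CYP51A1, TLR4 and GPX1 are uncertain in part, because reads were split with similar sequences or the gene overlaps another on the same strand.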

Results

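The series asked which cellular programmes depend on REST in endothelium. REST is the RE1-silencing transcription factor, a repressor best known for keeping neuronal genes off outside neurons. RNA-seq counts per gene were analysed for 4 libraries of human aortic endothelial cells that received REST siRNA and 4 that received a scramble siRNA. Library totals were 28387205 to 32327201 expected counts in the control group and 25787298 to 30392616 in the REST siRNA group. Mitochondrially encoded transcripts took 1.47% to 2.36% of the counts in control libraries and 1.79% to 2.7% in REST siRNA libraries. The first principal component held 69.4% of the variance and separated both groups. On the second, with 7.9% of the variance, REST siRNA library 1 had a score of -34.2 and the other REST siRNA libraries scores of 8.66 to 17.2. That library also had the fewest genes with a count, 17948 against 18680 to 19284 in the other libraries.

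REST itself (ENSG00000084093.16, GRCh38 chromosome 4, 56907876 to 56966678, plus strand) fell in the cells that received its siRNA. Its level was 39.6 ± 1.66 CPM in control cells (SD, n = 4) and 14.3 ± 1.94 CPM after REST siRNA (SD, n = 4). The control libraries read 41.8, 37.8, 39.7 and 39.3 CPM, and the REST siRNA libraries 16.5, 15.3, 13.4 and 12.1 CPM. The log2 fold change was -1.47 (SE 0.08, edgeR adjusted p = 1.99e-08), so that 36.2% of the transcript remained, with a 95% interval of 32.3% to 40.5%. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. Exons of REST overlap those of NOA1 on the other strand.

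Part of the genes that are nearly silent in endothelial cells and belong to neurons and neuroendocrine cells came on after REST siRNA. Of 34 measured members of a list of neuronal REST-repressed genes, 33 rose, each at least 2-fold, and 0 fell (33 and 0 adjusted over the list alone). The list held 61 genes, and the 27 removed by the low-count filter were below 1 CPM in both groups, so that a silent member was measured only where it came on. Of all 51 listed genes below 1 CPM in control cells, 23 reached at least 1 CPM after REST siRNA and 28 did not. The median log2 fold change of the measured members was 5.95. Setting NPPB, which had no control count, to its bound could not move this median, because the bound lies above it. UNC13A, a synaptic vesicle priming factor, went from 0.15 ± 0.101 to 204 ± 5.4 CPM (log2 fold change 10.35, SE 0.12, adjusted p = 1.08e-14). The granin-family secretory protein CHGB rose from 0.307 ± 0.145 to 103 ± 6.34 CPM, and STMN3, a regulator of microtubules, from 5.07 ± 0.769 to 194 ± 6.9 CPM. SCG3, another granin, reached 79.2 ± 3.48 CPM from 0.0566 ± 0.0425 CPM. BDNF did not pass (log2 fold change 0.27, adjusted p = 0.357). Camera gave the list an adjusted p of 1.4e-21, and it was the 1 list that also passed with an estimated correlation (adjusted p = 0.000777).

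**Figure D1:**
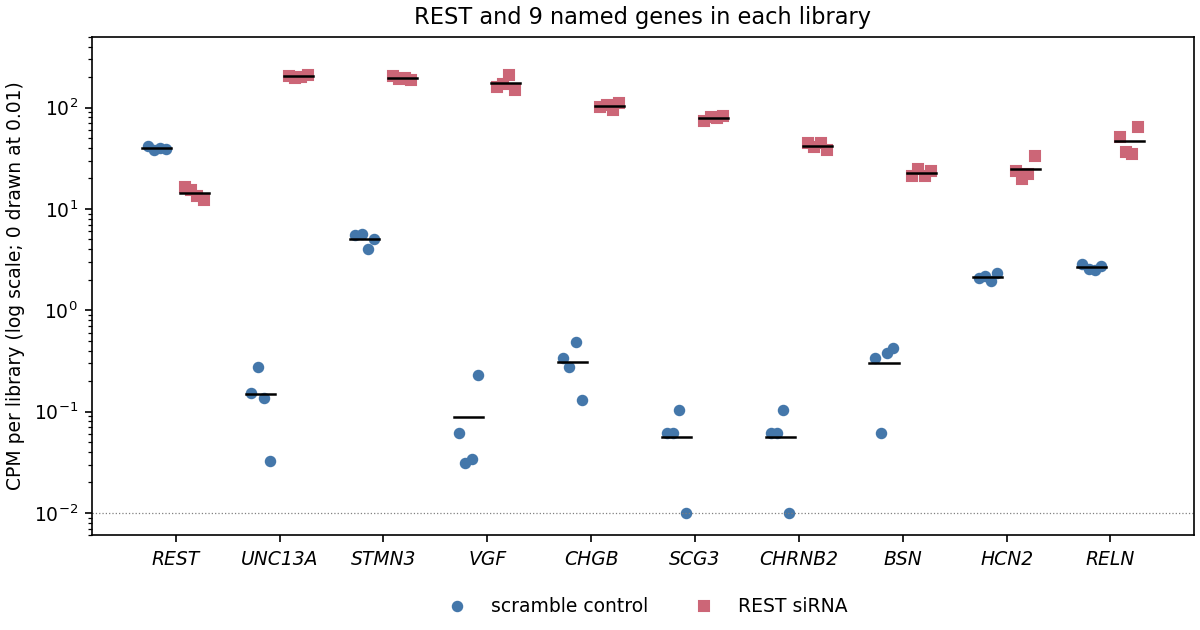
CPM of REST and 9 named genes in each library on a log axis, with circles for the 4 scramble control libraries, squares for the 4 REST siRNA libraries and black lines for group means. REST lies lower in all 4 REST siRNA libraries, near 14.3 against 39.6 CPM, and the other genes lie higher in all 4, UNC13A at 204 against 0.15 CPM.

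The 10 largest rises by the naming rule were VGF, SCG3, UNC13A, PTPRN, ACTL6B, XKR7, NPPB, TMEM198, CHRNB2 and KCNK3. VGF, which encodes a secreted neuropeptide precursor, reached 173 ± 27.5 CPM from 0.0887 ± 0.0939 CPM (log2 fold change 10.87, SE 0.22, adjusted p = 9.94e-13), and its control mean was 0.0422 CPM without control library 4. CHRNB2, a nicotinic acetylcholine receptor subunit, reached 42.2 ± 3.56 CPM from 0.0566 ± 0.0425 CPM. No count in any control library was seen for PTPRN, a protein of dense-core vesicles with GCAATTC in its 3' UTR, which was at least 226-fold higher. The same held for ACTL6B, a neuronal chromatin remodelling subunit, at least 199-fold, for NPPB, the natriuretic peptide B gene, at least 162-fold, and for TMEM198, at least 127-fold. XKR7 had 2 counts over the control libraries, both in library 2, and a count ratio of 1241 (95% interval 343 to 10257). KCNK3, a potassium channel gene, had 1 count, in control library 3, and a ratio of 591 (106 to 23369).

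Other neuronal lists moved less uniformly, with 18 of 45 and 21 of 32 listed genes past the low-count filter. Of 18 measured neuronal ion channels and receptors, 10 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.61. HCN2, a pacemaker channel, rose from 2.13 ± 0.155 to 24.8 ± 5.97 CPM and CACNA1B from 0.0543 ± 0.0523 CPM (0.0314 without control library 1) to 1.7 ± 0.354 CPM. The dopamine receptor gene DRD2 had 2 control counts, both in library 2, and a ratio of 207 (95% interval 56.7 to 1712). Camera gave an adjusted p of 0.0148, but 0.263 with an estimated correlation and 0.909 once genes below a mean of 5 CPM were left out. Of 21 synaptic vesicle and exocytosis genes, 4 rose and 7 fell (4 and 7 adjusted over the list alone). BSN, a presynaptic scaffold, rose from 0.3 ± 0.163 to 22.7 ± 1.91 CPM and RIMS2 from 0.12 ± 0.0474 to 3.6 ± 0.955 CPM. SYT11 fell from 84.2 ± 2.59 to 32.8 ± 2.27 CPM, and RAB3D fell to 20.2 ± 1.73 from 29.5 ± 2.55 CPM, and the 3' UTRs of SYT11, RAB3D and also of BSN, which rose, hold the heptamer GCAATTC. That list's median was -0.11 and its mean 0.31, and it did not pass (camera adjusted p = 0.704).

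Changes reached far beyond neuronal genes. Of 14355 genes tested, 8008 (55.8%) changed, 3935 higher and 4073 lower after REST siRNA. A change of at least 2-fold was seen in 1222 genes, 662 higher and 560 lower, and of at least 8-fold in 115 higher and 22 lower. Without REST siRNA library 1, 7731 genes changed, 3751 higher and 3980 lower. The groups did not overlap in 50.3% of tested genes, against 2.86% by chance. The share of changed genes that were higher was 49.1% with TMM scaling and 37.3% (3024 higher, 5075 lower) with library size alone. With genes below a mean of 5 CPM left out, 484 genes changed at least 2-fold. Of 12443 tested genes with an annotated 3' UTR, 15.4% hold the heptamer GCAATTC or GTGTATC there. Both heptamers were picked as those most tied to a fall in a search over these same fold changes. Of the genes with either, 48.9% fell and 17% rose, and of those with neither 27.9% fell and 30.4% rose.

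**Figure D2:**
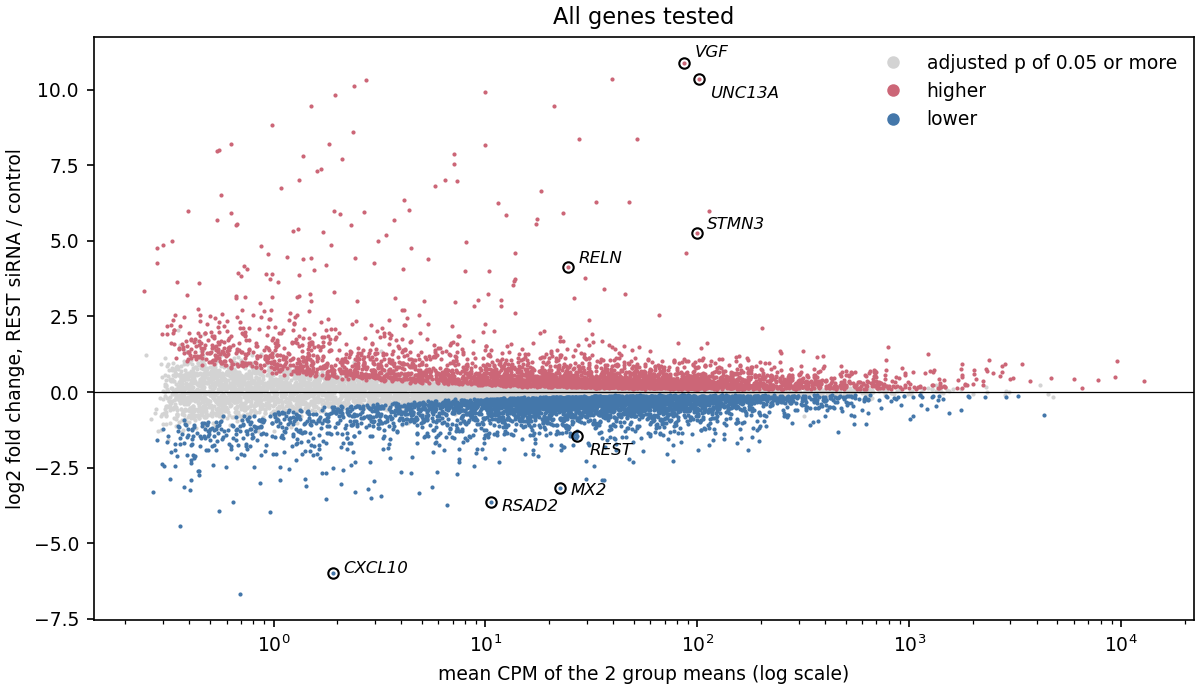
Log2 fold change of each tested gene (REST siRNA over control, edgeR) against its mean CPM on a log axis, with genes of adjusted p below 0.05 in red (3935 higher) and blue (4073 lower). Some named genes are circled, and the points at the top are genes near 0 CPM in control cells, whose fitted fold depends on the prior count.

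Interferon-stimulated genes were lower in REST siRNA cells. Of 43 measured members, 40 fell, 31 of them at least 2-fold, and 0 rose (41 and 0 adjusted over the list alone), with a median log2 fold change of -1.54. The chemokine CXCL10 went from 3.76 ± 1.31 to 0.0514 ± 0.0807 CPM (log2 fold change -5.98, SE 0.52, adjusted p = 7.71e-07). REST siRNA library 2 held 5 of its 6 counts in that group, and without it the mean was 0.012 CPM. The antiviral genes CMPK2, RSAD2 and MX2 had log2 fold changes of -3.72, -3.65 and -3.19 (MX2 -3.95 without REST siRNA library 4), and RSAD2 went from 19.7 ± 3.91 to 1.56 ± 0.578 CPM. IFIT3 fell from 63.7 ± 6.58 to 8.47 ± 2.53 CPM, and the transcription factor IRF1 from 28.1 ± 2.84 to 10.5 ± 0.865 CPM. IFI6, IFI27 and BST2 did not pass. Camera gave an adjusted p of 6.32e-13, and 0.691 with an estimated correlation, which was 0.62 among these genes. The 3' UTRs of 8 members, IRF1 among them, hold GCAATTC or GTGTATC, and 32 of the fallen members hold neither.

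The 10 largest falls also held CD79B, HIF3A, CX3CL1, CPXM1, CEND1 and AQP1. HIF3A, a member of the hypoxia-inducible factor family whose 3' UTR holds GCAATTC, fell from 5.3 ± 0.389 to 0.464 ± 0.209 CPM (log2 fold change -3.50, SE 0.24, adjusted p = 8.27e-08). The water channel gene AQP1 fell from 5.01 ± 0.702 to 0.541 ± 0.245 CPM. CD79B, CPXM1 and CEND1 had log2 fold changes of -3.53, -3.35 and -3.30. CX3CL1, an adhesive chemokine, fell from 5.85 ± 1.27 to 0.546 ± 0.444 CPM, or to 0.331 CPM without REST siRNA library 3.

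Genes of inflammatory activation fell more often than they rose. Of 40 measured, 20 fell and 7 rose (20 and 7 adjusted over the list alone), with a median of -0.38. VCAM1, a leukocyte adhesion molecule, fell from 65 ± 5.77 to 17.4 ± 3.89 CPM, the lipopolysaccharide receptor TLR4 from 96.7 ± 3.46 to 43.2 ± 1.87 CPM and IL1A from 19.3 ± 0.713 to 3.94 ± 2.14 CPM. BIRC3, an inhibitor of apoptosis, fell to 7.58 ± 1.81 from 22.2 ± 1.81 CPM. The 3' UTR of TLR4 holds GTGTATC. Camera gave an adjusted p of 0.0305, and 0.876 with an estimated correlation. The call was lost without control library 1 (0.0508), control library 4 (0.0602) or REST siRNA library 1 (0.0667), with library size alone (0.0871) and with genes below 5 CPM left out (0.0642).

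Cell-cycle genes were lower in REST siRNA cells. Of 46 measured proliferation genes, 43 fell and 0 rose (46 and 0 adjusted over the list alone), with a median of -0.52 and 2 of them at least 2-fold lower. CDC20, an activator of the anaphase-promoting complex, fell from 138 ± 11.1 to 68.8 ± 8.61 CPM (SE of the log2 fold change 0.08, adjusted p = 4.52e-07). The mitotic transcription factor FOXM1 had a log2 fold change of -0.63, the helicase subunit MCM7 -0.56 and the mitotic kinesin KIF11 -0.83. Camera gave an adjusted p of 6.82e-09, and 0.691 with an estimated correlation.

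Mesenchymal and matrix genes were mostly higher. Of 36 measured genes of mesenchymal cells and endothelial-to-mesenchymal transition, 23 rose and 4 fell (23 and 5 adjusted over the list alone), with a median of 0.51. ACTA2, smooth muscle actin, rose from 27.3 ± 1.04 to 70.7 ± 3.19 CPM, the collagen gene COL1A2 from 55.5 ± 11 to 152 ± 19.9 CPM, COL5A1 from 218 ± 20.1 to 396 ± 25.2 CPM and CCN1 from 755 ± 49 to 1160 ± 24.1 CPM. FN1, ZEB1 and PDGFRA did not pass, at log2 fold changes of -0.16, -0.02 and 0.03. Camera gave an adjusted p of 0.00893, and 0.691 with an estimated correlation. Among 42 extracellular matrix and adhesion genes, 24 rose and 10 fell (24 and 10 adjusted over the list alone). The integrin genes ITGA5 and ITGA10 rose, from 1964 ± 130 to 3720 ± 184 CPM and from 51.2 ± 3.24 to 104 ± 5.34 CPM, COL5A2, which holds GTGTATC, had a log2 fold change of 0.56, and ITGB4 fell from 16.1 ± 2.49 to 6.42 ± 0.533 CPM. The matrix list's camera adjusted p was 0.0293, but 0.691 with an estimated correlation and 0.127 when genes with either heptamer were left out, a check added after seeing the data. Of 7 fibroblast markers, 5 rose and 0 fell (6 and 0 adjusted over the list alone). COL3A1, COL1A1 and DCN had log2 fold changes of 1.17, 1.12 and 1.04, and DCN reached only 3.94 ± 0.792 CPM. COL1A1, COL1A2 and COL3A1 are also on the mesenchymal list and DCN is on the matrix list, so these lists are not separate results. Fibroblast markers had a camera adjusted p of 0.0324, 0.691 with an estimated correlation and 0.0701 without a low-count filter.

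**Figure D3:**
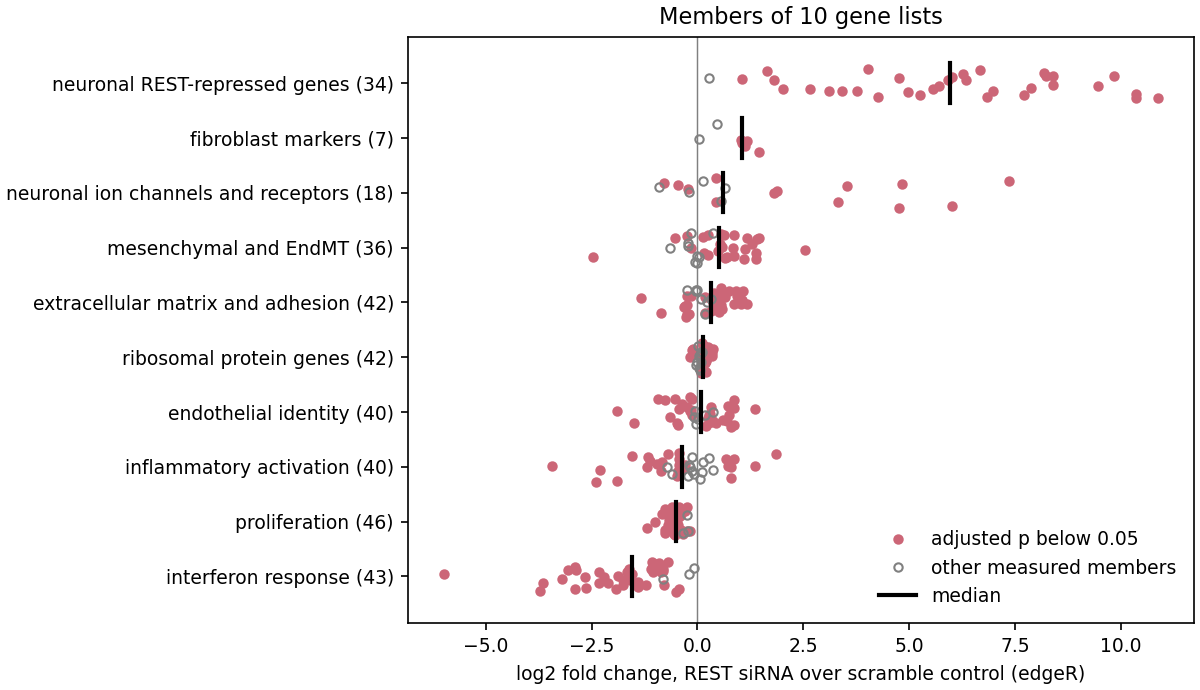
Log2 fold changes (REST siRNA over control, edgeR) of the measured members of 10 lists, with filled points for adjusted p below 0.05, open points for the others, black bars for list medians and the number measured in brackets. Neuronal REST-repressed genes have a median of 5.95, interferon genes of -1.54 and proliferation genes of -0.52, while endothelial identity genes scatter around 0.09.

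Endothelial identity genes changed in both directions. Of 40 measured, 18 rose and 16 fell (19 and 16 adjusted over the list alone; 18 and 19 with library size alone), with a median of 0.09 (camera adjusted p = 0.576). The surface protein gene CLEC14A rose from 138 ± 4.85 to 352 ± 22.4 CPM, and the endothelial transcription factor ERG from 133 ± 1.84 to 219 ± 9.34 CPM. GATA2 fell from 54 ± 1.65 to 31.5 ± 2.11 CPM and MMRN2 from 404 ± 6.43 to 278 ± 9 CPM, and both 3' UTRs hold GCAATTC. Of 6 lymphatic endothelial markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone). RELN rose from 2.66 ± 0.174 to 46.6 ± 14 CPM, LYVE1 from 2 ± 0.597 to 7.86 ± 1.52 CPM and FLT4 from 2.49 ± 0.427 to 6.3 ± 1.11 CPM, whereas SEMA3D had a log2 fold change of -0.82. PROX1, the lymphatic transcription factor, read 0.725 and 0.792 CPM and did not pass. The lymphatic list missed the threshold (camera adjusted p = 0.0716) and passed with library size alone (0.0317).

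Signalling and vascular lists were mixed. Of 40 TGF-beta and BMP genes, 14 rose and 10 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.704). The BMP receptor gene BMPR2, whose 3' UTR holds both heptamers, fell from 173 ± 7.85 to 67.6 ± 6.67 CPM (log2 fold change -1.36, SE 0.06, adjusted p = 3.65e-09). ACVRL1 had a log2 fold change of 0.51 and SMAD5 of -0.47. Of 34 genes of vascular tone and haemostasis, 14 rose and 12 fell (15 and 14 adjusted over the list alone; 14 and 16 with library size alone), with a median of -0.05 and a mean of 0.10 (camera adjusted p = 0.704). TFPI2, a serine protease inhibitor, rose from 76 ± 10.5 to 329 ± 38.7 CPM, the natriuretic peptide receptor gene NPR1 from 4.15 ± 0.361 to 13.4 ± 0.969 CPM and ECE1 from 997 ± 20.6 to 1586 ± 50.7 CPM. Of 45 Notch and angiogenesis genes, 23 rose and 9 fell (23 and 9 adjusted over the list alone). APLN, the apelin gene, had a log2 fold change of 0.76, NRP2 0.55, STAB1 0.48 and NOTCH2 -0.80. Camera gave the Notch list an adjusted p of 0.148, and 0.0375 with genes below 5 CPM left out.

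Genes near loci associated with coronary artery disease also went both ways, 15 higher and 15 lower of 46 measured (16 and 16 adjusted over the list alone; 14 and 20 with library size alone), with a median of -0.03, a mean of 0.04 and a camera adjusted p of 0.98. LIPA, lysosomal acid lipase, rose from 66.3 ± 0.903 to 137 ± 8.14 CPM. SWAP70 fell from 271 ± 3.09 to 120 ± 11.1 CPM, FGD6 from 25.6 ± 1.13 to 10 ± 0.609 CPM and PDGFD from 26.4 ± 3.26 to 6.99 ± 0.807 CPM, and the 3' UTRs of SWAP70, FGD6 and PDGFD hold at least 1 of both heptamers. Of 35 sterol synthesis and lipid uptake genes, 7 rose and 12 fell (7 and 12 adjusted over the list alone; camera adjusted p = 0.497). The sterol enzyme genes MSMO1 and CYP51A1 had log2 fold changes of -1.33 and -0.85, and the sterol carrier gene STARD4 fell from 59.8 ± 1.4 to 29.9 ± 2.66 CPM. Each of these holds GCAATTC in its 3' UTR. FABP4, a fatty acid binding protein gene whose 3' UTR holds GTGTATC, rose from 12.6 ± 1.52 to 28.6 ± 4.66 CPM. Of 23 REST corepressor genes, 4 rose and 7 fell (4 and 7 adjusted over the list alone; 2 and 9 with library size alone; camera adjusted p = 0.576). CTBP2 fell from 91.9 ± 3.9 to 43.8 ± 3.74 CPM, PHF21A, which holds GTGTATC, had a log2 fold change of -0.57 and EHMT1, which holds GCAATTC, one of 0.31. Of 12 neighbours of REST at 4q12, 5 rose and 4 fell (5 and 4 adjusted over the list alone; 3 and 4 with library size alone), with a median of -0.09, a mean of 0.20 and a camera adjusted p of 0.885, ARL9 going from 0.427 ± 0.0722 to 2.07 ± 0.73 CPM and IGFBP7 having a log2 fold change of 0.69.

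Stress and metabolic lists did not pass as lists. Of 30 genes of the unfolded protein and integrated stress response, 12 rose and 9 fell (13 and 10 adjusted over the list alone; camera adjusted p = 0.497), with PDIA6 and CALR at log2 fold changes of 0.56 and 0.49 and the cystine transporter gene SLC7A11 at -0.78. Hypoxia and glycolysis genes numbered 11 higher and 10 lower of 30 (11 and 10 adjusted over the list alone; camera adjusted p = 0.86), with EPAS1 at 0.65, PFKL at 0.55 and PGAM1, whose 3' UTR holds GTGTATC, at -0.60. Among 30 genes of the p53 response and senescence, 15 rose and 8 fell (15 and 8 adjusted over the list alone; camera adjusted p = 0.338). TP53I3 had a log2 fold change of 1.02, XPC of 0.63, and TP53INP1, with both heptamers, of -1.27. Oxidative stress genes numbered 11 higher and 8 lower of 26 (11 and 8 adjusted over the list alone; camera adjusted p = 0.704), with GPX1 at 0.69, PRDX4 at 0.81, TXNRD1 at -0.68 and GSR, which holds GCAATTC, at -0.72. The medians of the unfolded protein, oxidative stress and TGF-beta lists were 0.07, 0.03 and 0.07, and turned to values below 0 with library size alone. With that scaling the higher and lower genes numbered 10 and 10 in the unfolded protein list, 8 and 10 in the oxidative stress list and 9 and 13 in the hypoxia list. Hypoxia genes had a median of -0.04 and a mean of 0.06, and unfolded protein genes a mean of -0.05.

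Ribosomal protein genes were slightly higher, 29 up and 3 down of 42 (29 and 3 adjusted over the list alone; 17 and 4 with library size alone), with a median of 0.13 that was 0.05 with library size alone. RPL11, which holds GCAATTC, RPS19 and RPL3 had log2 fold changes of 0.37, 0.33 and 0.25. Camera gave an adjusted p of 0.000179, and 0.691 with an estimated correlation. Of 13 mitochondrially encoded transcripts, 1 rose (0 adjusted over the list alone), MT-ND3 at 0.28, and the list did not pass (camera adjusted p = 0.576). Immediate early genes numbered 7 higher and 7 lower of 22 (8 and 7 adjusted over the list alone; 3 and 8 with library size alone; camera adjusted p = 0.704), with JUNB at -1.13 and JUND at -0.53. Of 10 replication-dependent histone genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.704), H2BC5 at 1.48, H1-2 at 0.49 and H2AC6, with GTGTATC, at -0.46. The call of H2AC6 was lost without control library 1 (adjusted p = 0.082) or REST siRNA library 1 (0.0556), and that of H1-2 after a GC and length correction (0.07). The histone median was 0.02, and -0.05 with library size alone.

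Smooth muscle, epithelial, leukocyte and glial markers were measured in small numbers. Of 6 smooth muscle markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.704), with MCAM at a log2 fold change of 0.75 and RGS5, which holds GCAATTC, at -1.76. Among 6 epithelial markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone; 1 and 2 with library size alone; camera adjusted p = 0.86), CLDN7 at 0.60. Of 4 measured leukocyte markers, too few for a list test, ITGAX fell from 2.92 ± 0.893 to 0.451 ± 0.268 CPM and CD68 had a log2 fold change of 0.38 (1 higher and 2 lower adjusted over the list alone, and likewise with library size alone). MBP, the 1 measured glial marker, whose 3' UTR holds GCAATTC, read 0.613 ± 0.136 and 1.01 ± 0.294 CPM and did not pass (adjusted p = 0.0604; 1 higher adjusted over the list alone), but passed without REST siRNA library 1 (0.0193).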

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

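In 246 groups of 4 libraries, made of the CPM of the named genes reported here and 6 library measures, 16 (6.5%) held a library whose gap to the nearest of the others was above Dixon's 95% limit for its share of the group's range. Chance flags about 5% of groups of normally distributed values. A group with counts in a single library is always flagged, as for DRD2, XKR7 and KCNK3 in control, so the shares do not compare directly. No technical or biological explanation was tested for the flagged groups.

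Control library 1 read 5.72 CPM for CXCL10 against 2.96 to 3.19 in the other control libraries, 20.4 CPM for IL1A against 18.8 to 19.1, and 77.2 CPM for JUNB against 68.7 to 70.1. Its 10 most abundant genes took 6.8% of its counts against 6.26% to 6.33%. Control library 2 read 162 CPM for BMPR2 against 176 to 178, 1.85 CPM for FLT4 against 2.64 to 2.78 and 19.9 CPM for ITGB4 against 14.6 to 15.1. It also held the only control counts of DRD2 and XKR7, 0.0618 CPM each. In control library 3, CYP51A1 was at 83.1 CPM against 76.5 to 77.5, and KCNK3 had its only control count, 0.0343 CPM. VGF in control library 4 was at 0.228 CPM against 0.0309 to 0.0615 in the others.

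In the REST siRNA group, library 1 had a score of -34.2 on the second principal component against 8.66 to 17.2 in the others. Library 2 read 796 CPM for GPX1 against 867 to 879, 5.03 CPM for RIMS2 against 3.05 to 3.27 and 158 CPM for SRP72 against 139 to 142. Leaving out the library concerned changed none of these genes' calls.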

How the results depend on the processing

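The GC and length correction and the removal of genes with GCAATTC or GTGTATC were chosen after seeing the data. The fall of REST stayed past the threshold under all alternatives run, with log2 fold changes from -1.54 to -1.37 and adjusted p from 4.58e-58 to 2.6e-07. Genes changed numbered 8008, 7961 with DESeq2 (7846 of them shared) and 8027 with voom, and 7241 to 7731 with 1 library left out. With 1 library left out, 7112 to 7385 of the calls were shared, with no shared call changing direction. Of the 8008, 6960 were called in the same direction after the GC and length correction and 1 in the other. The number of genes changed at least 2-fold went from 1222 to 484 with genes below a mean of 5 CPM left out, because many of the large changes are in genes of low mean level that were no longer tested. The share of changed genes that were higher, 49.1%, was 37.3% with library size alone, which shifted the median log2 fold change of all genes from 0.00 to -0.08, 47.2% without a low-count filter and 46.2% after the GC and length correction. It was 53.5% without genes that hold either heptamer, which removes more fallen than risen genes. Lists passing numbered 9, 1 with an estimated correlation and 17 by fry, which does not compare a list with other genes. They numbered 7 to 9 under the other alternatives run for lists, which leave out DESeq2, voom and the GC and length correction. Of 1944 values of 123 named genes under alternatives, 1940 kept their side of the threshold and their direction, 3 were weaker and 1 stronger, and 120 genes never moved. H1-2 lost its call after the GC and length correction, and H2AC6 without control library 1 (adjusted p = 0.082) or REST siRNA library 1 (0.0556). MBP passed without REST siRNA library 1 (0.0193). No paired analysis was run, because the labels tie no replicate number to a column and do not say that the column numbers pair libraries. The mitochondrial share was highest in number 2 and lowest in number 4 of both groups. It was 2.36% and 1.47% in control, and 2.7% and 1.79% in REST siRNA, so a pairing by column number stays open. Depth limits genes under about 0.1 CPM, where a control group with no count gives only a bound.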

Other observations

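The tests of interferon genes without either heptamer, the graded site lengths, the matches shifted by 1 base, the whole REST-repressed list and the genes named below as chosen later were set after the results were seen. Beyond protein-coding genes, long non-coding RNAs and pseudogenes were more often higher than lower after REST siRNA. Of 1087 long non-coding RNAs tested, 238 rose and 120 fell, and of 508 pseudogenes 109 rose and 39 fell. Among 12676 protein-coding genes, 3574 rose and 3904 fell. The difference between gene types was not tested.

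More genes fell than rose, 4073 against 3935, although REST is known as a repressor. This balance rests on the scaling. With DESeq2 size factors 4013 fell and 3996 rose, and with library size alone 5075 fell and 3024 rose. At least 2-fold changes went the other way, 662 higher and 560 lower, and without the genes that hold either heptamer named next 3609 rose and 3136 fell. Sequence in the 3' UTR marked the falling genes. GCAATTC had a z of -12.4 over 1145 genes and GTGTATC one of -11.52 over 961 genes, against a lowest z of -4.80 in 100 permutations. Another 6 heptamers lay below that limit, TGTATCA the lowest at -6.71, and 1, GGAGAAA, lay above the highest permuted z of 4.81, at 5.18. Longer matches went with larger falls, from a median log2 fold change of -0.27 for GCAATTCA and -0.26 for GTGTATCA to -0.01 and -0.03 for their 6-base cores CAATTC and TGTATC. Either heptamer was present in 17 of the 20 and 70 of the 100 fallen genes of smallest adjusted p, against 15.4% of genes. Among all 3877 fallen genes 24.2% hold one, and 34.3% of those at least 2-fold lower. Genes so marked and chosen after their values were seen include UBE2V1 (log2 fold change -1.74), GNB4 (-1.75, 4 sites), TNFSF10 (-2.27), LIFR (-2.46) and SAMHD1 (-2.29). RAB8B, LIMCH1 and DHH are the exceptions among the 20. Both heptamers were picked by their z in these same fold changes, and the 15.4% is not matched for 3' UTR length. The shares of fallen genes with either heptamer, and the 3609 against 3136 without such genes, follow in part from that choice. So does the order of medians by match length, since the 6-base classes hold only genes without the longer matches. None of these is separate evidence.

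Each heptamer occurs once in the longest REST transcript, in coding sequence. GCAATTC lies at GRCh38 chromosome 4, 56930381 to 56930387, in exon 4 of 4, and GTGTATC at 56911385 to 56911391 in exon 2. This alone says little, because 30.3% of all heptamers occur in that transcript and both of a given pair would by chance in 9.18% of cases. A hypothesis is that siRNA guide strands act on other transcripts through their seed. It could have failed against -4.80, and z = -12.4 fits it. The graded matches add no separate evidence for it, because the heptamers were picked in these same fold changes. The siRNA sequences were not given in the sources used here, and the heptamers were not compared with a microRNA catalogue. Removing trends on GC content and length left 4301 genes lower against 4073, which argues against such a bias as the whole cause. Seed matches of the REST-repressed microRNAs miR-124, miR-9 and miR-132 had a z of -1.62, -0.32 and 0.05. None reached -4, and all lay above -2, the limit set beforehand for no such effect. The z of miR-124 lay within 1 of -2, too near that limit for the test to decide, so a part for these microRNAs stays open. Direct matches would account for an excess of 401.9 of 3877 fallen genes, or of 596.9 with the shifted heptamers CAATTCA and TGTATCA counted too, neither corrected for the longer 3' UTRs of genes with a match. Since 2358 fallen genes hold none of the 4 heptamers, indirect effects, a response to REST loss or to the lost transcripts, remain open and untested.

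Interferon genes fell together. PTPRC, an abundant leukocyte transcript, had 4 counts over the control libraries, an upper 95% limit of 0.0821 CPM, LYZ had 4 and TYROBP 0, which argues against leukocytes in the control cultures. Other genes of the leukocyte list were present there, LAPTM5 at 74.1 CPM and CD68 at 33.2 CPM, and ITGAX fell (log2 fold change -2.67), for which no source was tested. The 35 members with neither heptamer had a median log2 fold change of -1.60 and an upper quartile of -0.89, and the 27 without the shifted heptamers either a median of -1.40, which argues against direct matches in these genes as the whole cause. IRF1 (-1.42) and TLR3, a sensor of double-stranded RNA chosen after its value was seen (-2.45, SE 0.12, adjusted p = 3.65e-09, 14.9 ± 1.24 to 2.71 ± 0.388 CPM, n = 4), do hold a heptamer, and a loss upstream could lower the rest, which was not tested. Stimulation by the scramble siRNA cannot be told apart from a fall caused by REST siRNA, since each group had 1 reagent and no untreated library was analysed here (IFNB1 had 3 counts over the control libraries).

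Some neuronal genes silent in control cells appeared after REST siRNA. Of all 61 genes of the REST-repressed list, 51 were below 1 CPM in control cells, and 23 of these reached at least 1 CPM after REST siRNA, with a median of 0.403 CPM and an upper quartile of 14.3 CPM over the 51. Of 46 abundant neuronal and neuroendocrine genes outside that list, 26 were below 1 CPM in control cells, and their median after REST siRNA was 0.0099 CPM with 25 still below 1 CPM. The exception, CAMK2B, went from 0.896 to 2.75 CPM, and among the 25 SNCB and OLFM1 rose, to 0.811 and 0.887 CPM. DCX, GAP43, STMN4 and INSM1 were among the 25, at 0 to 0.0099 CPM. This argues against neuronal or neuroendocrine cells mixed into the cultures. Derepression after REST loss stays as a hypothesis that was not tested.

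The number of changed genes was largest in the real split. Among the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 8008. The highest of the others gave 0. Each of the others puts libraries of both groups on each side, so the difference between groups adds to the spread there. A low number in them follows from this, and the comparison cannot exclude chance. For the number of lists chance cannot be excluded. The real split gave 9 lists, 6 of the 35 splits gave as many, and the highest of the others gave 11. However, 16 of the other splits set 3 libraries of a group and 1 of the other on a side and so keep part of the real contrast. Of the 18 with 2 libraries of each group on a side, 1 gave as many, and the REST-repressed list passed in 0, the interferon list in 7 and the proliferation list in 9. The interferon list passed camera in 23 other splits of any kind and the proliferation list in 24, and the estimated correlations among their genes were 0.62 and 0.769. The absolute median was larger in the real split than in any other for 7 of the 9 lists, among them REST-repressed genes (5.95 against 1.53), interferon genes (1.54 against 0.96) and proliferation genes (0.52 against 0.39). It was not for inflammatory activation (0.38 against 0.45) and neuronal ion channels (0.61 against 0.72). Some lists that did not pass had their largest median in the real split too. Among them were endothelial identity (0.09 against 0.06) and Notch and angiogenesis (0.20 against 0.18), but not TGF-beta and BMP signalling (0.07 against 0.13). Splits that mix both groups shrink a group difference, so a larger median in the real split does not set the passing lists apart.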
